A study of Mus musculus with 6 samples.

How the data were processed

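RNA of sorted EGFP-positive cells of the mouse renal medulla was sequenced in 6 libraries, 3 from sham-operated and 3 from IRI mice. Per the labels' protocols, cells from 4 kidneys of 2 mice made each sample, the cells went through a cell sorter in 2 rounds, and total RNA was extracted with a kit for small amounts and amplified with SMARTer chemistry, which does not mark the strand. The labels do not say that samples of a group came from separate experiments, so p-values measure the spread between these pooled samples. The samples were grouped by their titles.

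The deposited read counts are whole numbers per gene and were not normalized. Per the submitters' processing notes, the tools were STAR, HTSeq and edgeR and the genome build was mm9; versions, roles and gene models are not given in the sources used here. Counting ignored strand, per the file names, so reads of a gene and of an overlapping antisense gene cannot be told apart. The deposited RPKM values carry gene symbols and lengths for all 37583 gene identifiers, per the file headers. For genes with over 50 reads, the deposited RPKM equalled the count divided by the length and by an effective library size, which differed by at most 1.3e-07% between the outer percentiles of genes in a sample and was 0.917 to 1.09 of the gene total, so RPKM is not independent of the counts. Coordinates are not printed, because the reference annotation used here (GENCODE M21, on GRCm38) is of another build.

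Of all reads recorded in a sample, 49.1% to 50.7% were counted in genes. The 5 entries that name no gene were left out of library sizes and tests. Reads without a unique alignment made up 39.9% to 42.4%, reads in no feature 7.29% to 7.81% in sham and 6.45% to 7.12% in IRI, and ambiguous reads 1.58% to 1.73%. Genes with near-identical copies lose reads this way or share them, which makes the values of Sprr2g, Acot3, Hsp90ab1, Eif4a1, Tubb2a, Tuba1c, Ddx3y and Eif2s3y uncertain. There were 14355 genes at 0 in all samples. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom 17.8 to 50.2, against 164 to 239.7 between groups), so no library was counted as a copy of another.

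Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr (13881 genes), libraries were scaled by TMM, and a quasi-likelihood model with a robust prior and the group as its only term was fitted to all 6 samples. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. The biological coefficient of variation was 19.0%. Standard errors of log2 fold changes were derived from the F statistic. CPM used TMM-scaled library sizes. For genes with at most 10 sham reads, the ratio of summed counts is given with an exact 95% interval, which covers counting error only, since PCR copies are not independent molecules.

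Before the data were examined, 38 gene lists (23 responses and 15 cell type markers), the test, the alternatives and the rule for named genes were fixed. Lists with at least 3 tested members (35) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Camera called 14 lists, camera with an estimated correlation 4 (cytokines, injury and repair, STAT3 and glucocorticoid-responsive genes) and fry 19. Some genes belong to several response lists, so these lists are not independent. Dusp1, Errfi1, Nfkbia, Lcn2, Pdk4 and Angptl4 of the glucocorticoid-responsive list are in other lists too, as are Gdf15, Plk2, Btg2, Fas and Bax of the p53 list. Hypoxia targets and glycolysis enzymes also share members. The rule named the 10 higher and 10 lower genes with the largest change, and the 5 higher and 5 lower with the smallest p, among called genes with a mean log2 CPM of at least 3, groups that did not overlap, and a symbol that is not a clone or predicted-gene name. It also named up to 4 called and 2 other members of each response list, up to 3 members of each marker list by level, and P2ry14, Atp6v1b1, Foxi1, Slc4a1, Slc26a4, Aqp2, Havcr1, Lcn2, Cx3cr1, Cxcl1, Cxcl2 and Ccl2. The list members described are a subset picked after their values were seen, and some genes that the rule names are not reported here. Genes that name the members behind small counts, and Spp1, Lyz2, Ptprc, Cyp4b1, Aqp6, S100a8, S100a9, Xist, Cldn4, Cldn7, Cldn8, Tubb2a, Tuba1c, Nr3c2, Hsd11b2, Eif4a1, C1qa, C1qb, C1qc, Tyrobp and Fcer1g, were chosen after their values were seen where the rule did not name them.

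The steps were tested on simulated counts with the real means and library sizes for IRI against sham. Of 13588 simulated genes tested, 66 of 100 changed 2-fold and 91 of 100 changed 4-fold were called, all 157 recovered genes had the right direction, and 5 of 13388 unchanged genes were called. Each set test called the planted list and 0 of 100 unchanged lists. The simulated genes varied independently of each other, and far fewer were changed than were called in the data. Estimated correlations in the data were, for example, 0.374 for immediate-early genes and 0.696 for oxidative phosphorylation genes. The simulation thus does not show how often the set tests call unchanged lists of correlated genes.

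The alternatives were median-of-ratios or upper-quartile scaling, no filter or a filter of 1 CPM in 3 samples, DESeq2 1.42.0, edgeR's exact test, limma-voom, limma on log2(RPKM + 1) for genes with a mean RPKM of at least 0.5 (with a pseudocount of 0.1, and without the filter), a prior that was not robust, the replicate number as a block, and leaving out each library. Scaling by library size alone was added after seeing the data. Folds on the log2(RPKM + 1) scale understate the change of low genes. Neighbouring genes were taken from the annotation by gene identifier, strand, order and distance, and 13420 of the tested genes (96.7%) were found in it. This gave 2391 same-strand pairs of tested genes at most 10 kb apart, in which genes under 2 CPM next to genes of at least 20 CPM in sham were compared by a two-sided permutation test with 100000 resamples. On random groups it found 20 of 20 planted rises of 1 log2 unit and 0 of 20 without one. Smaller planted rises were not tried, so its power for them is not known. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.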

Results

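Intercalated cells, the cells of the collecting duct that move acid and base across its wall, were studied early after kidney ischemia. RNA was sequenced from EGFP-positive cells that had been sorted in 2 rounds from the medulla of transgenic mice carrying EGFP with the B1 subunit of the vacuolar proton pump. The cells were taken 2 h after ischemia-reperfusion injury (IRI), in which the blood supply of the kidney is stopped and then restored, or 2 h after a sham operation. There were 3 sham and 3 IRI samples, and each sample pooled 4 kidneys from 2 mice aged 12 weeks. Sham replicates 1, 2 and 3 held 23061108, 22463419 and 17421669 reads counted in genes, and IRI replicates 1, 2 and 3 held 22805906, 24245330 and 22478011. Between 18621 and 18878 genes had at least 1 read in the sham libraries, and between 18935 and 19434 in the IRI libraries. Across genes, Spearman's rho was 0.983 to 0.990 between libraries of a group and 0.932 to 0.941 between groups (genes are not independent replicates). Levels are counts scaled to a common library size (CPM) as mean ± SD of n = 3 samples per group, and log2 values are fitted log2 fold changes of IRI over sham ± SE, tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment.

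Transcripts that mark intercalated cells were abundant in both groups. Carbonic anhydrase 2 (Car2) stood at 9443 ± 987 CPM in sham and 9558 ± 1192 CPM after IRI, the pump subunit Atp6v1g3 at 5392 ± 1152 and 5331 ± 390.0 CPM, and Foxi1, the transcription factor needed for intercalated cells to form, at 1189 ± 122 and 1523 ± 386 CPM. The chloride-bicarbonate exchanger of type A cells (Slc4a1) and the anion exchanger pendrin of type B cells (Slc26a4) were at 451 ± 76 and 2232 ± 555 CPM in sham. Transcripts of other tubule cells were abundant too. The water channel of principal cells, Aqp2, reached 9363 ± 329 CPM in sham and 6578 ± 2443 CPM after IRI. Uromodulin (Umod), of the thick ascending limb, reached 786 ± 213 and 629 ± 196 CPM. Gpx3, which was listed with the proximal tubule, stood at 7513 ± 1749.5 and 5154 ± 1734 CPM. Of the 25 markers in that list, 11 were below the filter on low counts, so Gpx3 does not stand for the list. The tissue entry of the labels reads epididymis and the genotype entry places EGFP under Cx3cr1 as well, while the design text describes renal medulla. Of 16 epididymis markers, 14 were below the filter on low counts, and Defb2 and Cst8 averaged 8.68 ± 2.98 and 1.42 ± 0.78 CPM in sham with no call (-0.86 ± 0.40, adjusted p = 0.114, and -0.29 ± 0.57, adjusted p = 0.712). Defb2 was called lower with library size alone (log2 -1.06, adjusted p = 0.0499) and without IRI replicate 3 (log2 -1.40, adjusted p = 0.00762). Cx3cr1 had 1 read in the sham libraries and 1 in the IRI libraries.

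**Figure D1:**
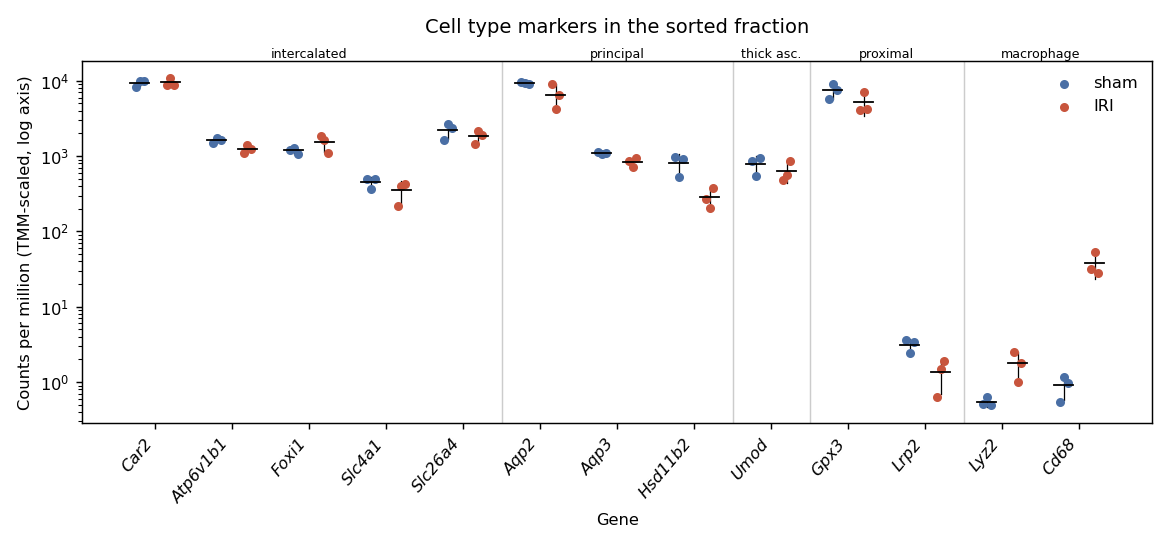
CPM of cell type markers in each sample (log axis), with sham in blue and IRI in red; points are samples, horizontal lines are means of n = 3 and vertical lines are 1 SD. Car2 and Aqp2 both sat near the top in sham, at 9443 ± 987 and 9363 ± 329 CPM, and Cd68 was 41.9-fold higher after IRI.

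The first question was which transcripts differed between cells from injured and sham kidneys. IRI changed the transcriptome of the sorted cells broadly: 3364 of 13881 genes tested were higher and 2948 were lower, together 45.5% of those tested. Among these, 1591 were at least 2-fold higher and 1180 at least 2-fold lower, while 266 were at least 8-fold higher and 32 at least 8-fold lower. Every IRI sample lay above or below every sham sample for 56.4% of the genes tested, where chance gives 10%. The first principal component separated the groups and held 71.1% of the variance. The division of the calls depended on scaling: 53.3% of called genes were higher as tested, 42.0% with upper-quartile scaling (2748 higher, 3789 lower) and 35.6% with library size alone (2400 higher, 4337 lower). Library size alone shifted the log2 fold changes of the tested genes by a median of -0.201 and upper-quartile scaling by -0.122, so small changes are relative to the scaling used. Where edgeR called 0 members of a list below in one direction, 0 were also called at an unadjusted p under 0.05 and by DESeq2, the exact test and limma-voom, except for Aqp6 and Cyp4b1.

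Among called genes with a mean log2 CPM of at least 3 and groups that did not overlap, Sprr2g rose the most. This small proline-rich protein, whose family members can share reads, rose 199.8-fold, from 0.792 ± 0.0742 to 161 ± 56.7 CPM (log2 7.64 ± 0.35, adjusted p = 1.09e-05). The heparan sulfate sulfotransferase Hs3st1 rose 72.5-fold (log2 6.18 ± 0.34, adjusted p = 1.94e-05), the nicotinic acid receptor Niacr1 49.9-fold (log2 5.64 ± 0.41, adjusted p = 8.59e-05) and the metalloprotease Adamts1 48.9-fold (log2 5.61 ± 0.47, adjusted p = 0.000204). Sprr1a (log2 5.55 ± 0.50), the calcium-binding protein S100a6 (5.40 ± 0.25), the EGF receptor ligand Hbegf (5.27 ± 0.38) and the urokinase receptor Plaur (5.25 ± 0.48) rose 38.2-fold to 46.9-fold. Hbegf went from 31.5 ± 7.63 to 1213 ± 457 CPM, and its adjusted p was 8.59e-05. Keratin 19 (Krt19) and the protease Prss22 were also among the 10 largest increases of such genes (log2 5.75 ± 0.90, adjusted p = 0.00471, and log2 5.38 ± 0.74, adjusted p = 0.00267). Krt19 varied widely between IRI samples, at 797 ± 803 CPM, and its log2 value was 4.47 without IRI replicate 2. Prss22 stood at 6.13 without sham replicate 1. The smallest p-values among the higher of these genes belonged to Dusp6, Cebpb, Cebpd, Ehd4 and Tnfrsf12a, with log2 values of 3.86 ± 0.13, 3.24 ± 0.11, 4.18 ± 0.15, 2.97 ± 0.12 and 4.94 ± 0.20 and adjusted p from 2.84e-06 to 4.93e-06.

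By the same conditions, the genes that fell the most included the aryl hydrocarbon receptor target Cyp1a1 and the acyl-CoA thioesterase Acot3. Cyp1a1 went from 101 ± 21.5 to 9.54 ± 4.75 CPM (log2 -3.41 ± 0.41, adjusted p = 0.000919) and Acot3 from 116 ± 23 to 13.6 ± 4.62 CPM (log2 -3.08 ± 0.28, adjusted p = 0.000183). Bsnd, which encodes barttin, was 7.85-fold lower (log2 -2.97 ± 0.16, adjusted p = 7.69e-06). The homeobox factor Hmx2 (log2 -2.95 ± 0.37, adjusted p = 0.00104), the kinase Fn3k (log2 -2.76 ± 0.31, adjusted p = 0.00027) and the potassium channel Kcnj13 (log2 -2.58 ± 0.21, adjusted p = 4.04e-05) fell as well. Igfbp5 (log2 -2.57 ± 0.42), the chemokine receptor Cxcr7 (-2.52 ± 0.41), Ipcef1 (-2.44 ± 0.28) and Emx1 (-2.36 ± 0.20) completed the 10 largest decreases, with adjusted p of 0.00372, 0.00289, 0.000312 and 4.94e-05. Without IRI replicate 3, Cxcr7 stood at -3.13. Those of the lower genes with the smallest p-values included, besides Bsnd, the secretory pathway kinase Fam20c (log2 -2.31 ± 0.11, adjusted p = 6.41e-06), the vesicle GTPases Rab3a (log2 -2.32 ± 0.11, adjusted p = 6.41e-06) and Rab17 (log2 -1.65 ± 0.09, adjusted p = 8.82e-06).

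**Figure D2:**
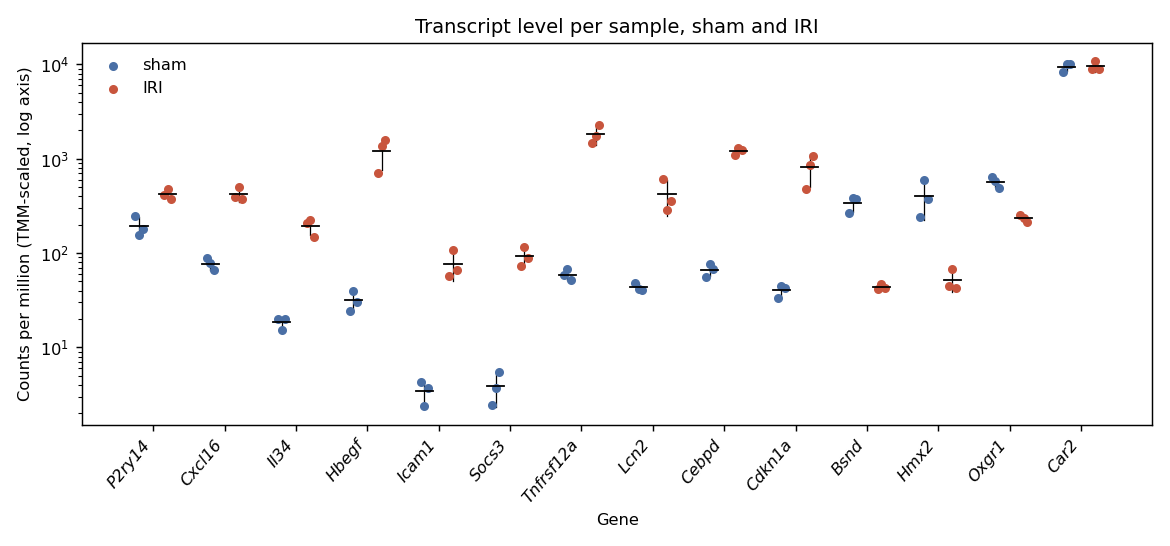
CPM of selected genes in each sample (log axis), with sham in blue and IRI in red; points are samples, horizontal lines are means of n = 3 and vertical lines are 1 SD. P2ry14 went from 195 ± 47 to 420.1 ± 49.6 CPM, Bsnd from 341 ± 65 to 43.3 ± 2.93 CPM, and Car2 lay at 9443 ± 987 and 9558 ± 1192 CPM.

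The study's title concerns P2Y14, the receptor for UDP-glucose and related UDP-sugars that is encoded by P2ry14. P2ry14 rose 2.16-fold after IRI, from 195 ± 47 to 420.1 ± 49.6 CPM (SD, n = 3 per group), and all 3 IRI samples lay above all 3 sham samples. Its log2 fold change was 1.11 ± 0.17 (SE), with an adjusted p of 0.00115. In the list of UDP-glucose and UDP-sugar genes, 12 of 30 tested members were higher and 6 were lower. UDP-glucose dehydrogenase Ugdh rose 4.24-fold (log2 2.08 ± 0.22, adjusted p = 0.00023), the galactosyltransferase B4galt1 8.99-fold (log2 3.17 ± 0.22, adjusted p = 1.98e-05) and phosphoglucomutase Pgm1 2.27-fold (log2 1.19 ± 0.10, adjusted p = 5.77e-05). As a set, the list did not stand apart from the other genes (camera, median log2 0.09, adjusted p = 0.155), and its median was -0.04 with upper-quartile scaling and -0.11 with library size alone, where 10 members were lower. Its members moved up on balance by fry, which does not compare them with other genes (adjusted p = 0.00338). Among purinergic receptors and ectonucleotidases, 6 of 15 tested members were higher and 2 were lower (camera adjusted p = 0.376). The adenosine receptors Adora2b (log2 2.69 ± 0.23, adjusted p = 5.38e-05) and Adora1 (log2 2.05 ± 0.22, adjusted p = 0.000301) rose. The ectonucleotidases Entpd3 (log2 -1.19 ± 0.35, adjusted p = 0.0232) and Nt5e (log2 -0.98 ± 0.15, adjusted p = 0.000829), which break down extracellular nucleotides, fell. The purinergic list had 5 members higher and 5 lower with library size alone. Entpd3 lost its call without sham replicates 1 or 2 or IRI replicate 1 (adjusted p up to 0.0703). Adjusted over the list alone, 12 UDP-sugar members were higher and 7 lower, and 7 purinergic members were higher and 4 lower.

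Most chemokine and cytokine transcripts tested were called higher. Of 18 chemokines tested, 12 were higher and 1, Ccl25, was lower. Of 19 cytokines and growth factors tested, 14 were higher and 2, Il15 and Tslp, were lower. Cxcl16 was the most abundant of the chemokines that rose, from 77.3 ± 11.4 to 420.3 ± 71.2 CPM (log2 2.44 ± 0.16, adjusted p = 1.52e-05). The neutrophil-attracting chemokines Cxcl1 and Cxcl2 went from 0.426 ± 0.227 to 18.6 ± 9.65 CPM and from 0.265 ± 0.176 to 11.5 ± 6.61 CPM (log2 5.46 ± 0.60, adjusted p = 0.000426, and log2 5.47 ± 0.62, adjusted p = 0.000389). Cxcl5 had 6 reads in the 3 sham libraries and 240 in the 3 IRI libraries, a ratio of 41.7 (95% counting interval 18.9 to 114.8), and its adjusted p was 8.82e-05. Il34, a ligand of the CSF1 receptor, rose 10.5-fold, from 18.5 ± 2.72 to 194 ± 39.6 CPM (log2 3.39 ± 0.19, adjusted p = 9.8e-06). Lif had 7 reads in the 3 sham libraries and 663 in the 3 IRI libraries, a ratio of 98.7 (95% counting interval 47.7 to 246.5), and Csf3 had 8 reads in the 3 sham libraries and 381 in the 3 IRI libraries, a ratio of 49.6 (95% counting interval 24.9 to 115.8), with adjusted p of 7.69e-06 and 6.45e-05. Ccl2, the monocyte chemoattractant, was below the filter, with 2, 2 and 0 reads in the sham libraries and 134, 1 and 18 in the IRI libraries. Both lists stood apart from the other genes by camera (chemokines, median log2 2.05, adjusted p = 7.7e-05; cytokines, median log2 2.94, adjusted p = 6.28e-09). With an estimated correlation the adjusted p was 0.101 for chemokines and 0.0413 for cytokines. Adjusted over the list alone, the counts were 12 higher and 1 lower for chemokines and 14 higher and 2 lower for cytokines. The calls of Ccl25 (log2 -0.65) and Tslp (-1.32) were lost without single libraries: Ccl25 without sham replicates 1 or 2 or IRI replicates 1 or 2 (adjusted p up to 0.1) and Tslp without sham replicate 2 or IRI replicates 1 or 3 (adjusted p up to 0.103).

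Of 15 macrophage and dendritic cell markers tested, 4 were higher (Cd68, Cd14, Lyz2 and Ptprc) and none was lower. Cd68 went from 0.903 ± 0.322 to 37.7 ± 14.2 CPM (log2 5.39 ± 0.37, adjusted p = 3.88e-05), Cd14, from 7.87 ± 2.52 to 32.7 ± 9.17 CPM (log2 2.05 ± 0.29, adjusted p = 0.000975), and lysozyme Lyz2, from 0.544 ± 0.0774 to 1.77 ± 0.753 CPM (log2 1.69 ± 0.42, adjusted p = 0.0103). Ptprc, the pan-leukocyte CD45, was at 10.2 ± 1.9 and 17.4 ± 1.55 CPM (log2 0.77 ± 0.17, adjusted p = 0.00588). Cd74, the invariant chain of class II molecules, had the highest level in the list, 120.2 ± 105 CPM in sham and 158 ± 64.5 CPM after IRI, with no call (adjusted p = 0.688). As a set, the list reached an adjusted p of 0.0555 by camera, 0.523 with an estimated correlation and 0.0169 by fry. The camera value was 0.00203 without sham replicate 3, 0.0334 without IRI replicate 2, 0.0323 without IRI replicate 3, 0.0423 with the stricter filter and 0.0104 with library size alone. None of 15 neutrophil markers passed the filter: S100a8 had 0 reads in each sham library and 40, 16 and 0 in the IRI libraries, and S100a9 had 0 in each sham library and 40, 12 and 0. Among 8 lymphocyte markers tested, 0 were called by edgeR's quasi-likelihood test, and also 0 at an unadjusted p under 0.05 and 0 by DESeq2, limma-voom or edgeR's exact test. Their median, mean and camera direction were negative and the fry direction positive (camera adjusted p = 0.853).

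Most tested members of the NF-kB, STAT3 and interferon lists were called higher. Of 27 NF-kB targets tested, 21 were higher and none was lower (camera, median log2 1.98, adjusted p = 2.97e-11, and 0.101 with an estimated correlation). The adhesion molecule Icam1 rose 22.2-fold, from 3.47 ± 0.952 to 77.1 ± 26.4 CPM (log2 4.47 ± 0.32, adjusted p = 5.33e-05), the NF-kB subunit Relb 8.93-fold (log2 3.16 ± 0.22, adjusted p = 2.87e-05) and the apoptosis inhibitor Birc3 4.71-fold (log2 2.24 ± 0.15, adjusted p = 1.86e-05). Sod2 had a log2 value of -0.11 ± 0.13 (adjusted p = 0.504) and was lower with library size alone (log2 -0.31, adjusted p = 0.0371). In the STAT3 and cytokine-signalling list, 16 of 19 tested members were higher and none was lower (camera, median log2 1.78, adjusted p = 1.56e-09, and 0.0413 with an estimated correlation). The feedback inhibitor Socs3 went from 3.88 ± 1.57 to 92 ± 20.9 CPM (log2 4.59 ± 0.31, adjusted p = 4.83e-05) and Stat3 itself rose 2.65-fold (log2 1.40 ± 0.11, adjusted p = 2.72e-05). The oncostatin M receptor Osmr had 5 reads in the 3 sham libraries and 900 in the 3 IRI libraries, a ratio of 187.7 (95% counting interval 80.1 to 579.3), with an adjusted p of 1.79e-05. Of 30 interferon-stimulated genes tested, 22 were higher and none was lower (camera, median log2 1.30, adjusted p = 1.56e-09, and 0.112 with an estimated correlation). The antiviral protein Rsad2 rose 10.2-fold (log2 3.34 ± 0.18, adjusted p = 8.44e-06) and the RNA sensor Ddx58 3.57-fold (log2 1.83 ± 0.12, adjusted p = 1.34e-05). In these lists 21, 16 and 24 members were higher adjusted over the list alone. In the same IRI samples, the myeloid marker Cd68 was 41.9-fold higher, while 11 of the 15 tested macrophage and dendritic cell markers had no call.

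Immediate-early genes, which cells transcribe within minutes of a stimulus, and feedback regulators of the MAP kinases were mostly higher. Of 38 immediate-early genes tested, 33 were higher and none was lower (camera, median log2 1.87, adjusted p = 2.88e-24, and 0.117 with an estimated correlation). The EGF receptor inhibitor Errfi1 rose 15.8-fold (log2 3.98 ± 0.18, adjusted p = 5.9e-06), the kinase Plk2 10-fold (log2 3.33 ± 0.18, adjusted p = 8.45e-06) and the AP-1 subunit Fosl2 6.65-fold (log2 2.73 ± 0.15, adjusted p = 8.45e-06). Fos and Jun, the classical members, were already at 376 ± 124 and 305 ± 69.8 CPM in sham and had log2 values of 0.34 ± 0.27 (adjusted p = 0.343) and 0.34 ± 0.28 (adjusted p = 0.358). Without IRI replicate 1, Jun was called higher (log2 0.60, adjusted p = 0.0426). Of 16 MAP kinase feedback regulators, 14 were higher and none was lower (camera, median log2 1.55, adjusted p = 2.38e-10, and 0.0629 with an estimated correlation). The ERK phosphatase Dusp6 went from 14.9 ± 2.18 to 216 ± 7.5 CPM (log2 3.86 ± 0.13, adjusted p = 2.84e-06), and Dusp14 rose 7.41-fold (log2 2.89 ± 0.20, adjusted p = 2e-05). The counts of higher members were 33 and 14 adjusted over the list alone.

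In the unfolded protein and integrated stress response list, 23 of 32 tested members were higher and 1, Aldh1l2, was lower (camera, median log2 1.07, adjusted p = 5.38e-08, and 0.241 with an estimated correlation). The transcription factors Cebpb and Atf4 rose 9.46-fold and 3.16-fold (log2 3.24 ± 0.11, adjusted p = 2.84e-06, and log2 1.66 ± 0.16, adjusted p = 7.91e-05). Asparagine synthetase Asns, a target of ATF4, rose 3.86-fold (log2 1.95 ± 0.18, adjusted p = 9.36e-05). Of 24 NRF2 targets, 16 were higher and 2, Gstm1 and Cbr3, were lower (camera, median log2 0.49, adjusted p = 7.62e-04, and 0.288 with an estimated correlation). With library size alone 12 were higher and 3 lower. Sulfiredoxin Srxn1 and thioredoxin reductase Txnrd1, which repair oxidised proteins, rose 4.64-fold and 3.06-fold (log2 2.21 ± 0.16, adjusted p = 2.02e-05, and log2 1.61 ± 0.11, adjusted p = 1.8e-05). In the glucocorticoid-responsive list, 14 of 17 tested members were higher and none was lower (camera, median log2 1.74, adjusted p = 8.72e-13, and 0.05, rounded up, with an estimated correlation, which kept the call). Cebpd rose 18.2-fold, from 66.7 ± 9.86 to 1213 ± 111 CPM. The metallothioneins Mt1 and Mt2 rose 3.02-fold and 6.08-fold (log2 1.59 ± 0.14, adjusted p = 5.12e-05, and log2 2.60 ± 0.18, adjusted p = 2.29e-05). Cytosolic heat shock genes went both ways, with 11 of 29 higher and 4 (Ahsa1, Chordc1, Fkbp4 and Hspa2) lower (camera adjusted p = 0.181, and 5.2e-05 without IRI replicate 1), or 9 higher and 6 lower with library size alone. The chaperone Hspa4 and the co-chaperone Bag3 rose (log2 0.91 ± 0.09, adjusted p = 7.32e-05, and log2 1.18 ± 0.14, adjusted p = 0.000227), the HSP90 co-chaperones Ahsa1 and Chordc1 fell (log2 -1.23 ± 0.10, adjusted p = 4.46e-05, and log2 -0.98 ± 0.14, adjusted p = 0.000667). Hsp90ab1 had a log2 value of 0.35 ± 0.20 (adjusted p = 0.185). Adjusted over the list alone, these 4 lists had 24, 16, 14 and 11 higher and 1, 2, 0 and 4 lower. Calls lost without single libraries were Aldh1l2 (log2 -1.52) without IRI replicates 1 or 3, Gstm1 (-0.62) without sham replicate 2 or IRI replicate 1, Hspa2 (-0.59) without sham replicate 1 or IRI replicate 2 and Fkbp4 (-0.49) without IRI replicate 1, with adjusted p up to 0.0549, 0.0687, 0.0576 and 0.051.

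Genes of the p53 response and of cell death moved in both directions, with more higher than lower. Of 25 p53 targets, 13 were higher and 4 (Bax, Sesn1, Xpc and Ddb2) were lower (camera, median log2 0.65, adjusted p = 0.00238, and 0.152 with an estimated correlation). With library size alone 12 were higher and 7 lower. The cell cycle inhibitor Cdkn1a rose 20-fold, from 40.3 ± 5.88 to 807 ± 304 CPM (log2 4.32 ± 0.32, adjusted p = 8.59e-05), Gdf15 6.99-fold (log2 2.81 ± 0.25, adjusted p = 0.00014) and the death receptor Fas 5.08-fold (log2 2.34 ± 0.25, adjusted p = 0.000151). The DNA repair genes Xpc and Ddb2 fell (log2 -0.88 ± 0.10, adjusted p = 0.000257, and log2 -0.75 ± 0.17, adjusted p = 0.00653), as did the stress-induced Sesn1 (log2 -1.01 ± 0.20, adjusted p = 0.00317). Among 29 cell death genes, 15 were higher and 7 were lower (camera, median log2 0.65, adjusted p = 0.00223, and 0.101 with an estimated correlation). The survival factor Mcl1 rose 5.34-fold (log2 2.42 ± 0.11, adjusted p = 6.41e-06), the necroptosis kinase Ripk3 9.12-fold (log2 3.19 ± 0.26, adjusted p = 4.88e-05), the TNF receptor Tnfrsf1a 3.2-fold (log2 1.68 ± 0.12, adjusted p = 1.86e-05) and the inflammatory caspase Casp4 9.93-fold (log2 3.31 ± 0.32, adjusted p = 9.36e-05). Members that promote and members that oppose cell death were thus both higher. The pro-apoptotic Bax was lower (log2 -0.36 ± 0.10, adjusted p = 0.0138) and lost its call without sham replicate 2 (adjusted p = 0.0579). There were 13 and 16 higher and 4 and 7 lower adjusted over the list alone.

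Tubular injury and repair genes had the largest median change of the lists tested. Of 30 tested members, 27 were higher and none was lower (camera, median log2 3.39, adjusted p = 3.44e-33, and 0.0211 with an estimated correlation), and 28 were higher adjusted over the list alone. Tnfrsf12a, the receptor for TWEAK, rose 30.7-fold, from 59.1 ± 7.89 to 1815 ± 409 CPM, annexin A2 (Anxa2) 12.5-fold, from 86.3 ± 5.53 to 1080.1 ± 253 CPM, and galectin 3 (Lgals3) 4.55-fold, from 771 ± 33.7 to 3506 ± 33.1 CPM (adjusted p = 4.93e-06, 6.41e-06 and 6.41e-06). Lcn2, which encodes the urinary injury marker NGAL, rose 9.64-fold, from 43.4 ± 4.28 to 419 ± 171 CPM (log2 3.27 ± 0.29, adjusted p = 0.000161). Havcr1, the proximal tubule injury marker KIM-1, was below the filter, with 3, 3 and 0 reads in the sham libraries and 7, 19 and 5 in the IRI libraries, and was called higher when no filter was applied (log2 2.35, adjusted p = 0.0407). Osteopontin (Spp1) was the most abundant transcript in all 3 IRI libraries, at 2.23%, 1.37% and 1.70% of gene counts (log2 1.26 ± 0.17, adjusted p = 0.000499).

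**Figure D3:**
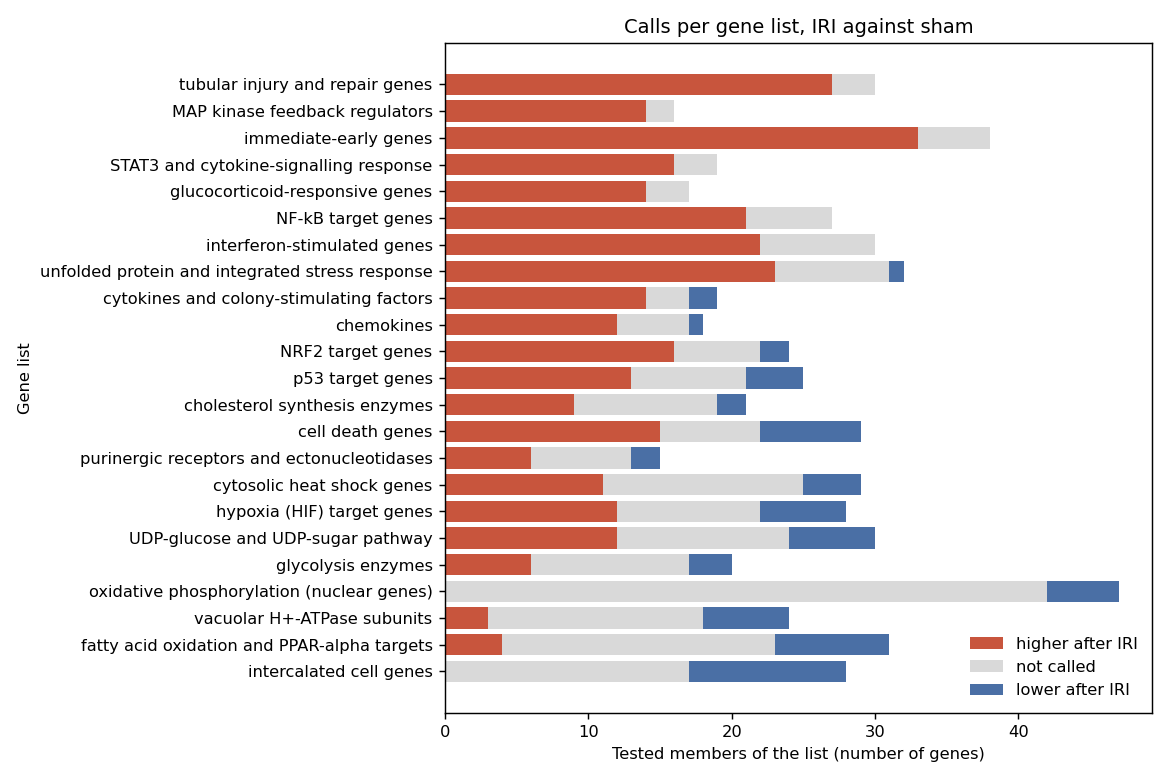
Number of tested genes in each response list that were higher after IRI (red), lower after IRI (blue) or not called (grey), with the lists ordered by higher minus lower calls per tested gene. Injury and repair genes had 27 of 30 higher, and intercalated cell genes had 11 of 28 lower and none higher.

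Genes that define intercalated cells were lower or not called. Of 28 tested, 11 were lower and none was higher (camera, median log2 -0.32, adjusted p = 0.00138, and 0.252 with an estimated correlation), with the same 0 and 11 adjusted over the list alone and 14 lower with library size alone. Besides Bsnd and Hmx2, the 2-oxoglutarate receptor Oxgr1 fell from 569 ± 72.4 to 233 ± 21.3 CPM (log2 -1.29 ± 0.13, adjusted p = 9.57e-05) and the transcription factor Tfcp2l1 from 664 ± 65.7 to 352 ± 25.2 CPM (log2 -0.91 ± 0.11, adjusted p = 0.000315). The B1 pump subunit Atp6v1b1, for which the transgene is named, was 1.3-fold lower (log2 -0.37 ± 0.13, adjusted p = 0.0427), a call lost without sham replicates 2 or 3 or IRI replicates 1 or 3 (adjusted p up to 0.119). Log2 values without a call were 0.02 ± 0.14 for Car2, 0.36 ± 0.19 for Foxi1, -0.36 ± 0.26 for Slc4a1 and -0.28 ± 0.22 for Slc26a4 (adjusted p = 0.934, 0.154, 0.288 and 0.326). Car2 was negative with upper-quartile scaling and with library size alone (log2 -0.11 and -0.18), and without IRI replicate 3 Foxi1 was called higher (log2 0.55, adjusted p = 0.0149). In the short type A list, 1 of 6 markers, Kit, was lower (log2 -0.80 ± 0.16, adjusted p = 0.00414), with a positive median (0.06, but -0.06 with upper-quartile scaling and -0.14 with library size alone) and mean (0.01) and a negative camera direction (adjusted p = 0.785), and in the type B list 1 of 3, Insrr, was lower (log2 -1.62 ± 0.34, adjusted p = 0.00835; camera adjusted p = 0.511). Both counts were the same adjusted over the list alone. Aqp6, a water channel of type A cells, went from 302 ± 71.1 to 556 ± 212 CPM without a call (log2 0.88 ± 0.32, adjusted p = 0.0604), and was called higher by DESeq2 (adjusted p = 0.00358), by the exact test (0.0102) and without IRI replicate 1 (0.00288). Principal cell markers were lower in the same samples for 3 of 11 tested: Hsd11b2, which inactivates glucocorticoids, Aqp3 and Kcne1 (log2 -1.51 ± 0.29, adjusted p = 0.00549, log2 -0.40 ± 0.12, adjusted p = 0.0273, and log2 -1.50 ± 0.35, adjusted p = 0.0123). As a set these had an adjusted p of 0.0664 by camera, 0.00868 without sham replicate 2, 0.0189 without IRI replicate 1 and 0.0273 without IRI replicate 3. Aqp2 had a log2 value of -0.51 ± 0.25 (adjusted p = 0.127) and was called lower without IRI replicate 1 (log2 -0.81, adjusted p = 0.0119), while Aqp3 lost its call without sham replicate 3 or IRI replicate 2 (adjusted p up to 0.064).

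Subunits of the vacuolar proton pump, which acidifies urine and organelles, mostly showed no call: of 24 tested, 3 were higher, 6 were lower and 15 were not called (camera adjusted p = 0.511). The subunits Atp6v0a1, Tcirg1 and Atp6v1b2 were higher (log2 1.59 ± 0.11, adjusted p = 1.94e-05, log2 1.03 ± 0.22, adjusted p = 0.00479, and log2 0.39 ± 0.12, adjusted p = 0.0233). Those lower were Atp6v0d1 (log2 -0.56 ± 0.13, adjusted p = 0.00698), Atp6v1g2 (log2 -0.81 ± 0.22, adjusted p = 0.014), Atp6v1c2 (log2 -0.87 ± 0.23, adjusted p = 0.0165), Atp6v1a (log2 -0.37 ± 0.11, adjusted p = 0.0247), Atp6v1d (log2 -0.37 ± 0.13, adjusted p = 0.0491) and Atp6v1b1. Atp6v1a lost its call without sham replicate 2 or IRI replicate 2, and Atp6v1d without sham replicates 2 or 3 or IRI replicates 1 or 3 (adjusted p up to 0.0699 and 0.139). With library size alone 2 were higher and 12 lower, and adjusted over the list alone 3 were higher and 4 lower. Atp6v1b2 lost its call without sham replicates 1 or 3 or IRI replicates 1 or 2 (adjusted p up to 0.0962), and with library size alone (log2 0.20, adjusted p = 0.194) or upper-quartile scaling (0.27, adjusted p = 0.087).

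Ppargc1a, the coactivator that drives mitochondrial gene expression, fell from 249 ± 33.9 to 105 ± 9.32 CPM (log2 -1.24 ± 0.13, adjusted p = 0.000111), and the electron transfer dehydrogenase Etfdh fell too (log2 -0.76 ± 0.09, adjusted p = 0.000314). In the fatty acid oxidation list, 8 of 31 members were lower and 4, among them Acadl, Pdk4 and Angptl4, were higher (camera adjusted p = 0.17). Pdk4, which restrains glucose oxidation, rose 3.9-fold (log2 1.96 ± 0.28, adjusted p = 0.00124), Acadl had a log2 value of 0.41 ± 0.10 (adjusted p = 0.00829) and Angptl4 one of 2.35 ± 0.62 (adjusted p = 0.0251). Of 47 nuclear genes of oxidative phosphorylation, 5 (Ndufa8, Sdhd, Ndufs7, Ndufs1 and Ndufb10) were lower, none was higher and 42 were not called (camera adjusted p = 0.105). Ndufa8 and Sdhd had the smallest p of these (log2 -0.57 ± 0.12, adjusted p = 0.00549, and log2 -0.54 ± 0.13, adjusted p = 0.00834). Both lists depended on scaling, with 25 oxidative phosphorylation genes and 16 fatty acid oxidation genes lower with library size alone, where the oxidative phosphorylation list reached an adjusted p of 0.00748. It was 0.00311 without sham replicate 1. Acadl was not called with library size alone (adjusted p = 0.0855). Ndufb10 lost its call without sham replicates 2 or 3 or IRI replicates 1 or 2 (adjusted p up to 0.101), Acadl without sham replicate 3 (0.0557) and Angptl4 without sham replicate 3 or IRI replicates 1 or 3 (up to 0.081), and without sham replicate 1 Angptl4 stood at 3.29. Adjusted over the list alone, 4 fatty acid oxidation genes were higher and 8 lower, and 4 oxidative phosphorylation genes were lower.

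Hypoxia targets, glycolysis enzymes and cholesterol synthesis enzymes did not stand apart as sets. Of 28 hypoxia targets, 12 were higher and 6 lower (camera adjusted p = 0.162, fry 0.0156). Bhlhe40 rose 7.7-fold (log2 2.95 ± 0.25, adjusted p = 9.69e-05) and the HIF hydroxylase Egln3 12.7-fold (log2 3.66 ± 0.41, adjusted p = 0.000188). Vegfa, a classical target, fell from 109.9 ± 4.63 to 66.7 ± 7.52 CPM (log2 -0.72 ± 0.11, adjusted p = 8e-04). Among 20 glycolysis enzymes, 6 were higher and 3 (Pfkl, Pfkm and Pgam2) were lower (camera adjusted p = 0.511, fry 0.00338), with a median of 0.09 as tested, which was -0.04 with upper-quartile scaling and -0.12 with library size alone, where 4 were higher and 3 lower. Eno2 and hexokinase 2 (Hk2) rose (log2 1.97 ± 0.22, adjusted p = 0.000182, and log2 4.00 ± 0.62, adjusted p = 0.00151), the latter to 6.78 ± 2.79 CPM and with a log2 value of 4.96 without sham replicate 2, and Pfkm fell (log2 -0.99 ± 0.14, adjusted p = 0.000681). Of 21 cholesterol synthesis enzymes, 9 were higher and 2 (Mvk and Dhcr7) were lower, with Sc5d 2.29-fold higher (log2 1.20 ± 0.20, adjusted p = 0.00176). This list had a camera adjusted p of 0.0664, which was 0.00373 without sham replicate 3, 0.0227 without IRI replicate 3 and 0.047 with library size alone. Adjusted over the list alone, 14 hypoxia targets, 6 glycolysis enzymes and 9 cholesterol enzymes were higher and 6, 3 and 2 were lower.

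Markers of the remaining cell types were mostly not called. Among 14 proximal tubule markers tested, 1, the endocytic receptor Lrp2, was lower (log2 -1.20 ± 0.40, adjusted p = 0.0373), and none was lower adjusted over the list alone (camera adjusted p = 0.668). Cyp4b1 had a log2 value of 0.78 ± 0.28 (adjusted p = 0.0508) and was called higher by DESeq2 (0.0379), the exact test (0.036) and limma-voom (0.0362), and without sham replicate 1 (0.0064). Gpx3 had a log2 value of -0.54 ± 0.26 (adjusted p = 0.123). It was called lower without IRI replicate 2 (log2 -0.87, adjusted p = 0.0131) and with library size alone (log2 -0.75, adjusted p = 0.0291). Of 10 thick ascending limb markers, Sostdc1 and Cldn19 were lower (log2 -1.75 ± 0.17, adjusted p = 9.79e-05, and log2 -0.85 ± 0.29, adjusted p = 0.0412), 1 of them adjusted over the list alone, and the list's adjusted p was 0.105, or 0.0143 without sham replicate 2 and 0.0139 without IRI replicate 3. Slc8a1 was lower among 6 distal convoluted tubule markers (log2 -1.43 ± 0.20, adjusted p = 0.000509; camera adjusted p = 0.521). Endothelial markers gave 1 higher, the VEGF receptor Flt1, and 1 lower, Ehd3, of 7 tested (camera adjusted p = 0.628). Flt1 (adjusted p = 0.00588) had 10 reads in the 3 sham libraries and 101 in the 3 IRI libraries, a ratio of 10.5 (95% counting interval 5.5 to 22.6), and its log2 value of 3.29 was 2.62 without sham replicate 1 and 4.51 without sham replicate 3. Ehd3 stood at -1.09 ± 0.21 (adjusted p = 0.00279). The smooth muscle genes Acta2 and Tagln were higher among 3 fibroblast and pericyte markers, at 3.31 ± 2.33 and 1.61 ± 0.916 CPM after IRI (log2 3.23 ± 0.66, adjusted p = 0.00472, and log2 1.50 ± 0.52, adjusted p = 0.0424; camera adjusted p = 0.576). Of 4 podocyte markers, 1 was higher, Synpo, and 1 lower (Synpo, log2 2.03 ± 0.33, adjusted p = 0.00117; camera adjusted p = 0.845), with 2 higher and 1 lower adjusted over the list alone. No erythroid marker passed the filter. The Y-linked Ddx3y and Eif2s3y were higher after IRI (log2 1.00 ± 0.17, adjusted p = 0.00152, and log2 0.73 ± 0.11, adjusted p = 0.00076; camera adjusted p for 4 sex-linked genes = 0.275, fry 0.0473), and Xist had 1 read in the sham libraries and 2 in the IRI libraries. Calls were lost for Lrp2 without sham replicates 1 or 3 or IRI replicates 1 or 2 (adjusted p up to 0.0914), Cldn19 without sham replicates 1, 2 or 3 or IRI replicates 1 or 2 (up to 0.101) and Tagln without sham replicates 1 or 3 or IRI replicates 2 or 3 (up to 0.178), and Acta2 stood at 2.56 without IRI replicate 3.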

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

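Scaling by library size alone was chosen after seeing the data; the other settings were planned. P2ry14 was called higher in every setting run, with log2 values from 0.90 to 1.29 (0.97 to 1.29 without single libraries). Between 2400 and 3444 genes were higher and between 2295 and 4337 lower across settings, and no gene called in one direction as tested was called in the other. Without single libraries, 2566 to 3172 were higher and 2295 to 2734 lower. Of 14 lists called, 4 were called with an estimated correlation. For cytokines and cell death genes the estimated correlation (0.002 and -0.003) lay below the preset 0.01. Their camera adjusted p still rose, from 6.28e-09 to 0.0413 and from 0.00223 to 0.101, so a higher correlation of the members is not the reason in these lists. Camera with an estimated correlation thus differs from camera at the preset one in more than the correlation used. For the other lists the cause was not tested. A larger adjusted p with an estimated correlation is therefore not read here as an effect of correlation among members. Of the called genes named, 128 of 147 kept the call whichever single library was left out and 19 lost the call in at least 1 such fit, while 7 of 22 uncalled genes gained one. With the other settings 133 to 147 of them were called. Genes with large changes are overrepresented among those named, so this is no rate for all genes. With no filter Kcne1 and Angptl4 were not called (adjusted p = 0.0597 and 0.0962), Tagln was not called with upper-quartile scaling, limma-voom, library size alone or RPKM, and DESeq2 called Aqp2 and Gpx3 lower (adjusted p = 0.0499 and 0.0439). Atp6v1d was not called with a prior that was not robust (0.0514) or by limma on RPKM without the filter (0.0656). That RPKM setting also left Acta2 (adjusted p = 0.0565), Atp6v1b1, Atp6v1b2, Ccl25, Tslp, Aldh1l2, Gstm1, Entpd3, Ndufb10, Lrp2, Cldn19 and Aqp3 without a call. Ccl2, Havcr1 and the neutrophil markers were below the filter; without it Ccl2, S100a8 and S100a9 had no call (adjusted p = 0.174, 0.224 and 0.236), and whether depth or the spread between libraries limits them was not tested.

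Signs turned only for values without a call, and the cause was not tested. Car2 was at -0.11 with upper-quartile scaling, -0.0199 with no filter, -0.0212 with each of the RPKM settings, and -0.18 with library size alone. With upper-quartile scaling and library size alone, C1qa was at -0.0014 and -0.091 and C1qb at -0.0476 and -0.16, and Atp6v1g3 was at 0.0028 with limma-voom. Without single libraries the log2 values ran from -0.20 to 0.14 for Atp6v1g3, -0.11 to 0.0734 for Car2, -0.0498 to 1.34 for Cd74, -0.48 to 0.59 for C1qa, -0.51 to 1.90 for C1qb, -0.83 to 2.46 for C1qc and -1.01 to 0.24 for Cst8. Camera directions turned for podocyte markers with the stricter filter (adjusted p = 0.859) and for lymphocyte markers with library size alone (0.754), and fry gave lymphocyte markers the other direction (0.95). Without single libraries, directions also turned for lists with adjusted p of 0.585 to 0.993 (type A markers), 0.553 to 0.915 (proximal tubule), 0.181 to 0.683 (distal convoluted tubule), 0.232 to 0.987 (lymphocyte) and 0.657 to 0.987 (podocyte).

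Sham and IRI samples share replicate numbers, but no label says that a number marks a shared animal, litter or day. Deviations from the group means correlated at 0.182, 0.095 and 0.178 across genes between samples of the same number, not all above 0.1. Every sample correlated best with its own number, but 3 samples per group can be matched in few ways, so this can easily arise by accident. It is at most a hint from the data and not from the design. With the replicate number as a block, 3368 genes were higher and 3095 lower, 17 lists were called (besides the 14, macrophage and dendritic cell, thick ascending limb and principal cell markers, adjusted p = 0.00891, 0.0242 and 0.00748), Slc26a4, Gpx3 and Defb2 were called lower (adjusted p = 0.0468, 0.00732 and 0.00771), Cyp4b1 was called higher (0.0325), P2ry14 stood at 1.13, Atp6v1g3 at 0.0038, and no call among the genes named was lost.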

Other observations

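The tests of myeloid cells, macrophages, the share of intercalated cells and the splits of the samples were chosen only after the result was seen, and so were the claudin, tubulin and mineralocorticoid genes. Of these tests, all but the splits replaced earlier forms, and the test of the share was rewritten more than once. The test of reads running past Eif4a1 was set before its result.

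The following genes were not tested as sets, and 45.5% of all genes tested were called. Claudins, which seal and select ions at tight junctions, went both ways: of 16 tested, 9 were higher and 3 lower, and with library size alone 7 were higher and 3 lower. Cldn4 rose 17.7-fold, from 72.2 ± 5.97 to 1278 ± 426 CPM (n = 3 per group, log2 4.15 ± 0.27, adjusted p = 3.3e-05), and Cldn7 rose 3.08-fold (log2 1.62 ± 0.13, adjusted p = 3.88e-05), while Cldn8 fell from 1361 ± 182 to 527 ± 114 CPM (log2 -1.37 ± 0.17, adjusted p = 0.000345). Of 10 tubulin genes tested, 9 were higher with each of the scalings run, among them Tubb2a (log2 1.89 ± 0.09, adjusted p = 6.6e-06) and Tuba1c (log2 2.19 ± 0.19, adjusted p = 6.86e-05), whose reads copies can share. The mineralocorticoid receptor gene Nr3c2 fell (log2 -1.41 ± 0.11, adjusted p = 2.93e-05), as did Hsd11b2 (-1.51 ± 0.29), whose enzyme keeps glucocorticoids from that receptor.

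The rise of chemokine and cytokine transcripts may come from myeloid cells carried through the sort. The 2 rounds of sorting for EGFP select against cells without it. Even so, transcripts of other tubule cells, such as Aqp2, were abundant in the fraction. The genotype label also places EGFP under Cx3cr1, whose own transcript had 1 read in the sham libraries and 1 in the IRI libraries. All 36 macrophage, dendritic cell and neutrophil markers together gained 98.0, 105 and 192 CPM in the 3 IRI libraries, and 2 of the 26 chemokine and cytokine transcripts called higher, Hbegf and Cxcl16, gained more than that in every IRI library. The other 24 did not, but scarce transcripts, such as Lif and Cxcl1 (mean gains of 10.1 and 18.15 CPM), could hardly gain as much whatever their source. The count of 24 thus does not bear on the source. The markers together reached 356 CPM in sham replicate 3, above IRI replicates 1 and 2 (289 and 296 CPM), so myeloid cells and a response of the sorted cells cannot be told apart. The most abundant marker, Cd74, stood at 120.2 ± 105 and 158 ± 64.5 CPM, and of the 36 markers 15 passed the filter and 0 are in another list. A response of intercalated cells to IRI, and transcripts from other tubule cells in the fraction, remain open and untested.

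Cd68 rose 41.9-fold, more than the other called macrophage markers, Cd14 (2.05 ± 0.29), Lyz2 (1.69 ± 0.42) and Ptprc (0.77 ± 0.17). The other 20 markers of its list together gained 194%, 90.8% and 613% of what Cd68 gained in the 3 IRI libraries, but stood at 355 CPM in sham replicate 3, and Lyz2, C1qa, C1qb, C1qc, Tyrobp and Fcer1g, picked after their values were seen, gained at most 8.94%, so macrophages may or may not be the source and stay open. Reads running past the end of Eif4a1, the neighbour just upstream (log2 1.11 ± 0.10, adjusted p = 6.73e-05), are a candidate explanation: 152 low genes downstream of a well expressed gene had a median log2 change of 0.171 and 136 upstream of one had -0.09, a difference of 0.261 (permutation p = 0.15). But 31 of the 152 and 28 of the 136 were called higher, and 11 and 12 had a log2 value of 3 or more, so large rises like that of Cd68 were not more frequent downstream. Per kilobase, Cd68 stood at 0.978, 1.48 and 0.784 of Eif4a1 in the 3 IRI libraries, so read-through, macrophages and a rise of Cd68 in the sorted cells cannot be told apart from gene counts.

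The fall of 11 intercalated cell genes (median log2 -1.01) was weighed against a lower share of intercalated cells, which would lower all genes of the list by about the same factor. Around 1 common change, the squared deviations of all 28 genes were 21.4 squared SE per degree of freedom, and those of the 11 among themselves 22.4. The genes thus did not share 1 common change, which argues against a lower share as the only cause. No other list was put through this test, so it is not known whether other lists spread as far, and 45.5% of all genes tested were called. The spread therefore does not tell whether the share fell in part. Bsnd (-2.97 ± 0.16) and Atp6v1b1 (-0.37 ± 0.13) lay far apart among the 11. The other 17 genes had a median of 0.006, from -0.527 to 0.88, with Atp6v1g3 at -0.02 ± 0.17, Car2 at 0.02 ± 0.14 and Foxi1 at 0.36 ± 0.19. They were set apart by having no lower call, so their median was largely fixed by that choice and is no separate evidence. A lower share as a part of the fall, and changes of expression within intercalated cells after IRI, stay open and were not tested apart.

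Of the 10 splits of the 6 samples into 3 and 3, the real one called 6312 genes and the highest of the others 1. Only 1 split, the real one, thus called as many, but 10 splits are too few for a share under 0.05. Every other split mixed sham and IRI samples, so the difference between sham and IRI widened the spread within its sides. Few calls were likely there for that reason, and the low counts do not bear on chance.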
